A study of Mus musculus with 6 samples.

How the data were processed

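Exome capture libraries of genomic DNA from 6 primary tumour-derived lines of C57BL/6 mice were compared, 3 from Rag1KO and 3 from WT hosts. Per the labels' protocols, tumours were dissociated, the cells were cultured, and libraries were made with a mouse exome panel from Twist. The submitters' processing notes name BWA 0.7.17, SAMtools, GATK 4.2.3.0 and the build mm10, without their roles. The program that made the copy ratio tables is not given in the sources used here. Variant calls were not analysed here.

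Each deposited table held, for the same 242275 bins, a coverage signal (mean read depth), a log2 ratio and a score (a weight per bin), per the file headers. The deposited log2 ratio followed the log2 of the deposited coverage less a constant per sample, with an SD of 0.030 to 0.042 around that relation. No correction against normal DNA was therefore visible, so capture efficiency, repeated gene families and sex chromosomes remain in the values. Bins at depth 0 carried a deposited log2 placeholder near -27.6 to -28.0. The tables give mean depth and not read counts, so no counting intervals were computed.

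Of these bins, 231587 lay on autosomes, 8922 on X, 1268 on Y, 43 on the mitochondrial genome and 455 on unplaced contigs. Bins with a mean depth of at least 10 over the 6 samples were kept (241099). The median over autosomal bins was subtracted per sample (-0.07 to 0.02). The log2 ratios were given a lower bound of -5 before centring, a choice made after the placeholders were seen. The use of the placeholders as deposited was added as an alternative.

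A bin was assigned to each protein-coding gene span (GRCm38.p6, the assembly of mm10) that held its midpoint. This gave 21234 genes by symbol, of which 19903 had at least 3 bins, and 5295 bins counted for more than 1 gene. Gene values were means weighted by the deposited score. Windows of 1 Mb with at least 3 bins were summarised by their median (2320 windows, 2167 of them on autosomes). Segments came from least-squares partitioning of window medians with a penalty of 10 noise variances per added segment. A segment counted as altered when its mean was at least 0.2 from 0.

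WT lines were compared with Rag1KO lines with limma 3.58.1 (R 4.3.3) for genes and windows, with Benjamini-Hochberg adjustment at 0.05. Single values were compared with exact two-sided permutation tests (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Plots were drawn with matplotlib 3.10.9. For chromosomes and lists, p was adjusted over 20 chromosomes and 10 lists. The lists held 187 genes, of which 184 were measured. They covered oncogenes, tumour suppressors, the MYC network, interferon gamma signalling, MHC class I antigen presentation, glycolysis, mitochondrial respiration, amino acid uptake and serine synthesis, death receptor and NK ligand genes, and DNA repair.

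Groups, tests, lists and most alternatives were fixed before the data were examined. Named genes were Rag1 and Rag2; list members that were called, that had no overlap and a difference of at least 0.3 (at most 3 per list), or that had a deep loss or high gain in a line; the 10 genes with the largest difference without overlap (at most 2 per chromosome); and, per line, the 3 most extreme deep losses (at or under -1.5) and high gains (at or over 1.0) with an assigned name, at most 1 per 5 Mb. Symbols of the forms Gm, Rik and LOC were passed over, and LOC was added to that rule after the data were seen. The result of 1 gene chosen by this rule is not reported here. For the chromosome and list comparisons, the effect of the alternatives was followed as the number of chromosomes or lists whose groups did not overlap. Depth-based values, centring, bin filters, window sizes, thresholds, left-out lines and other tests were tried as alternatives.

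The gene test was tested on simulated data in the same 3 against 3 design over 19903 genes. In a single run it recovered 51% of differences of 1.0 and 1% of differences of 0.3, with 1 false call among the unchanged genes. Noise was drawn for each gene separately, whereas real genes on the same chromosome share its copy ratio. A 3 against 3 comparison at this spread therefore misses most small differences. The partitioning recovered 100% of simulated steps of 0.4, with 0.045 false breakpoints per chromosome, at a window noise SD of 0.07. Real windows also hold deviations that several lines share, and WT 6 had 181 segments though it lay near 0 on most autosomes. The simulated rate of false breakpoints therefore does not carry over to the segment counts of the lines. Between any pair of lines, 0.283% to 0.558% of bins had identical depth, so no line was taken for a second copy of another.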

Results

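Genomic DNA from 6 primary tumour-derived cell lines of C57BL/6 mice was captured with a mouse exome panel and sequenced. The series asks how the genomes of tumour cells grown in immunocompetent and immunocompromised hosts differ. Of the lines, 3 came from Rag1KO mice, which lack a gene that T and B cells need to rearrange their receptors (lines 1, 3 and 7), and 3 came from wild-type (WT) mice (lines 2, 4 and 6). The values were copy ratios over 242275 capture bins with a median length of 135 bp on mm10. Median depth per bin was 195, 177 and 217 reads in Rag1KO 1, 3 and 7, and 183, 197 and 227 reads in WT 2, 4 and 6. The labels number the lines but do not say that each came from a separate mouse, so p-values measure the spread between these lines. With 3 lines against 3, an exact two-sided permutation test cannot go below p = 0.1.

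The Rag1 gene was lost in part in all 3 Rag1KO lines and intact in all 3 WT lines. Rag1 (gene ID 19373, chromosome 2, 101638252 to 101649532, mm10) held 12 capture bins. In the Rag1KO lines, 4 neighbouring bins spanning 101643234 to 101644274 (1041 bp) were listed at depth 0, against 177.5 to 313 reads in the WT lines. On both sides, 2 bins had reduced depth of 42.0 to 73.8 in the Rag1KO lines, against 135 to 246 in the WT lines. The mean copy ratio over Rag1 was -1.95 ± 0.02 (log2, SD, n = 3) in the Rag1KO lines and 0.01 ± 0.03 in the WT lines, a difference of 1.97 (SE 0.07, limma adjusted p = 0.00163) with exact permutation p = 0.1. The mean over the 6 remaining Rag1 bins was between -0.11 and 0.02 in every line. Rag2, the neighbouring gene whose product works with Rag1, was at 0.01 ± 0.01 and -0.04 ± 0.05 (limma adjusted p = 0.9999, WT minus Rag1KO -0.05). Rag1 matched the label in 6 of 6 lines. The annotation used gives gene spans, so exons and UTRs were not assigned. The size of the Rag1 difference depends on the lower bound of -5 set for bins at depth 0, and was 9.52 with the deposited placeholder values.

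**Figure D1:**
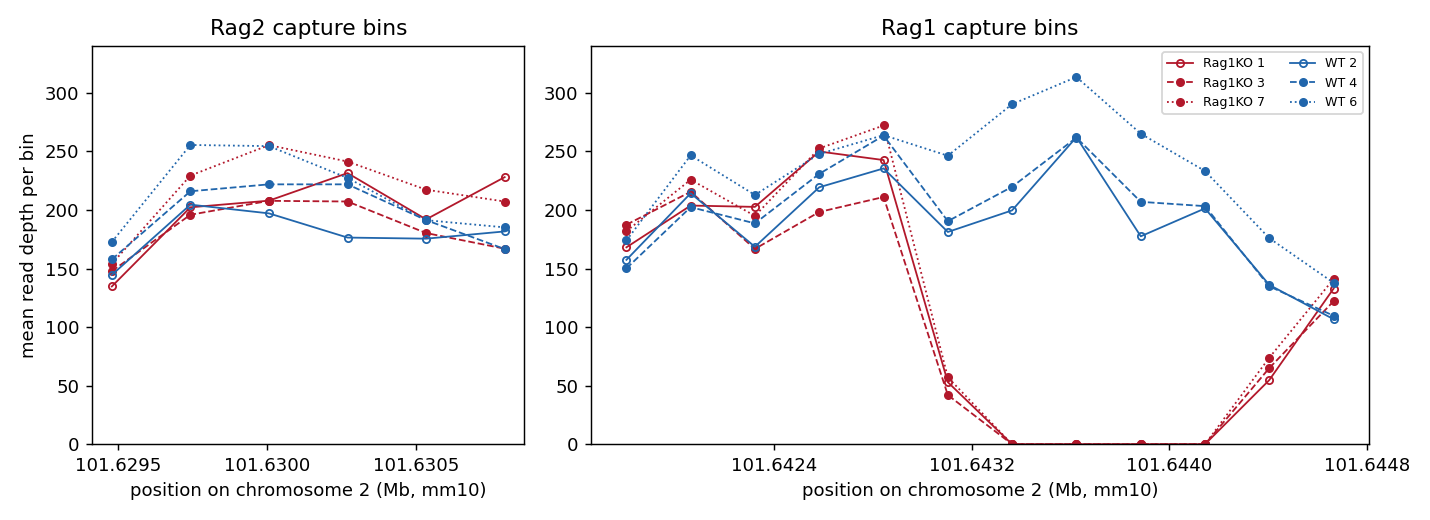
Mean read depth per capture bin (vertical axis) against position on chromosome 2 in Mb (horizontal axis) over Rag2 (left) and Rag1 (right), with 1 line per cell line, red for Rag1KO and blue for WT. The Rag1KO lines drop to 0 in 4 Rag1 bins where the WT lines stay between 177.5 and 313 reads.

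Across 19903 protein-coding genes, Rag1 was the only gene called as different in copy ratio between lines from Rag1KO and WT hosts. It is the gene that defines the host groups, so its difference checks the labels and is not a finding about tumour growth in these hosts. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator p19Arf, had the largest difference among genes whose groups did not overlap (gene ID 12578, chromosome 4, 89274473 to 89294619). Its copy ratio was -0.67, -0.29 and -0.11 in Rag1KO 1, 3 and 7 and -0.95, -4.99 and -3.97 in WT 2, 4 and 6. Of the other genes chosen for the largest difference without overlap, Saa3 and Crxos on chromosome 7 and Dynlt3 and C1galt1c1 on X were lower in the Rag1KO lines. Chromosome 7 as a whole had a lower mean in the Rag1KO lines (-0.42) than in the WT lines (-0.19). The differences of Saa3 and Crxos are therefore not shown to be particular to these genes. X as a whole also had a lower mean in the Rag1KO lines (-0.87) than in the WT lines (-0.17). Dynlt3 did not follow X line by line. It was at 0.83 in WT 6, where X was at -1.01, and at 0.49 and 0.29 in Rag1KO 3 and 7, where X was at -0.90. The groups of C1galt1c1 were barely apart, with -1.098 in WT 6 and -1.106 in Rag1KO 7. Retnlb and Olfr177 on chromosome 16 and Morf4l1b on chromosome 19 were lower in the WT lines. Chromosome 16 as a whole was also lower in the WT lines (-0.20) than in the Rag1KO lines (0.03), while chromosome 19 was not (0.22 and 0.20). The differences of Retnlb and Olfr177 are thus not shown to be particular to these genes either.

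By limma, 1 of 19903 genes passed an adjusted p of 0.05, while 107 had an unadjusted p under 0.05. Cdkn2a differed by -2.94 (WT minus Rag1KO, SE 0.98), with a limma adjusted p of 0.9999 (0.217 to 0.99998 over its alternatives). Its size depends on the lower bound for bins at depth 0 and was -16.2 with the deposited placeholder values. The differences of the 7 further genes were 0.39 (Saa3), 0.38 (Crxos), 0.85 (Dynlt3), 0.83 (C1galt1c1), -0.37 (Retnlb), -0.35 (Olfr177) and -0.997 (Morf4l1b), and none passed. Olfr177 and Morf4l1b have close relatives in the genome, and their values are uncertain for that reason. Morf4l1b was at 0.35, 0.26 and 1.22 in Rag1KO 1, 3 and 7 and at 0.08, 0.13 and -1.37 in WT 2, 4 and 6, and its difference was -0.50 without WT 6. Without Rag1KO 1 the differences of Crxos and Dynlt3 were 0.21 and 0.50, and without WT 2 that of C1galt1c1 was 0.50. In all, 528 genes (2.65%) had groups that did not overlap, against 10% given by chance. Genes on the same chromosome share its copy ratio and are not independent, so the lower share is not read as a depletion. Rag1 lost its call with trend and robust variance estimates (limma adjusted p = 0.9999) and with the median of bins (1.18, limma adjusted p = 0.118). Without WT 6 the count was 829 genes, of which 808 lay on X, 20 on Y and 1 (Rag1) on an autosome.

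The lines carried gains and losses of whole chromosomes or large parts of them, several of them in lines from both hosts. Chromosome 10 had a median copy ratio of 0.80 in Rag1KO 1, 0.61 in Rag1KO 3, 1.05 in WT 2 and 0.43 in WT 4, and lay at -0.00 and -0.05 in Rag1KO 7 and WT 6. In WT 4 the chromosome was uneven, with segment means of 0.05 from 3000001 to 14000000, 0.04 from 58000001 to 68000000 and 0.54 from 105000001 to 113000000, and narrow peaks between them. Chromosome 15 was at 0.39, 0.61 and 0.16 in Rag1KO 1, 3 and 7 and at 0.59, 0.28 and -0.04 in WT 2, 4 and 6. Chromosome 4 was at -0.74, -0.39 and -0.07 in the Rag1KO lines and -0.41, -0.38 and -0.06 in the WT lines, and chromosome 7 at -0.70, -0.34 and -0.22 against -0.35, -0.22 and 0.01. Chromosome 19 was high in Rag1KO 7 (0.46) and WT 6 (0.55).

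Further chromosomes lay at least 0.2 from 0 in 1 or more lines. Chromosome 12 was at -0.91 in Rag1KO 7 and -0.21 in WT 4, chromosome 8 at -0.36 in Rag1KO 3, chromosome 16 at -0.38 in WT 2 and chromosome 17 at 0.37 in WT 4. Chromosome 3 was at -0.38 in Rag1KO 3 and -0.39 in WT 2. WT 4 also had chromosome 6 at 0.23, chromosome 9 at -0.21 and chromosome 13 at -0.23, and Rag1KO 1 had chromosome 14 at -0.24. X was at -0.81, -0.90 and -0.90 in the Rag1KO lines and at 0.36, 0.13 and -1.01 in WT 2, 4 and 6. Y bins had a median depth of 66.6, 90.2 and 63.0 in the Rag1KO lines and 114 in WT 6, and were at 0 in WT 2 and WT 4. The sex chromosomes thus differed between lines and partly followed the host groups. X over 0 went with no Y reads, and X at -1.01 to -0.81 with Y reads. Loss of Y alone would leave X at the lower level, so the X values of WT 2 and WT 4 argue against it in these lines. A difference in sex between the mice would give this pattern and was not tested. A host difference on X or Y cannot be told apart from this pattern.

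None of the 20 chromosomes separated the host groups. Group means differed most on X, at -0.87 ± 0.06 (SD, n = 3) in the Rag1KO lines and -0.17 ± 0.74 in the WT lines (exact permutation p = 0.4, adjusted p = 1). Chromosome 16 had the smallest p, with means of 0.03 ± 0.11 and -0.20 ± 0.17 (exact permutation p = 0.2, adjusted p = 1). In 1 Mb windows, limma called 0 of 2320, with 9 at an unadjusted p under 0.05, and 0 with trend and robust variance estimates, where 16 had an unadjusted p under 0.05. Without WT 6, limma called 151 windows, all on X.

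**Figure D2:**
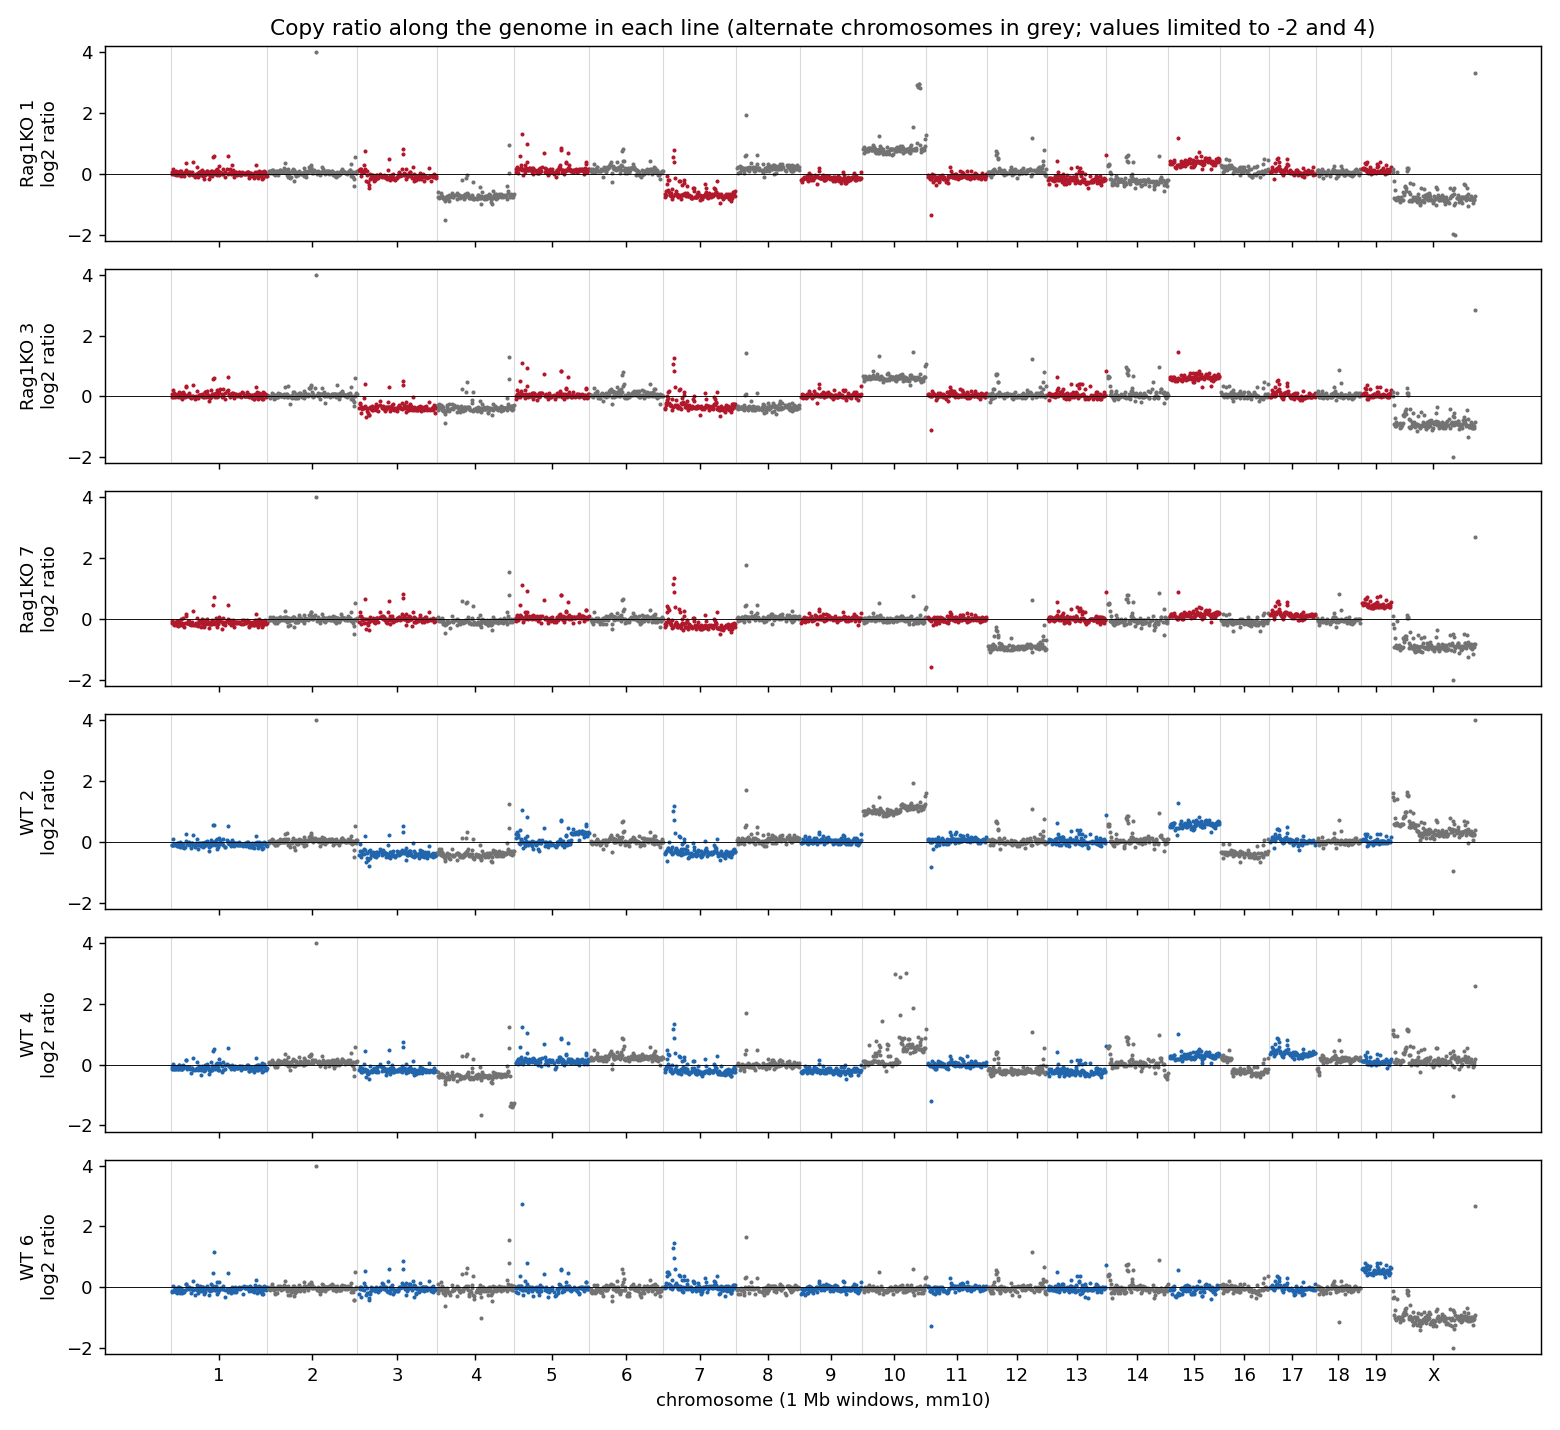
Median log2 copy ratio of 1 Mb windows (vertical axis, limited to -2 and 4) along chromosomes 1 to 19 and X (horizontal axis), with 1 panel per line and 1 point per window. Points are red for Rag1KO and blue for WT, with alternate chromosomes in grey. Chromosome 10 is raised over its length in Rag1KO 1, Rag1KO 3 and WT 2, and WT 6 lies near 0 on most autosomes apart from chromosome 19 (0.55).

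**Figure D3:**
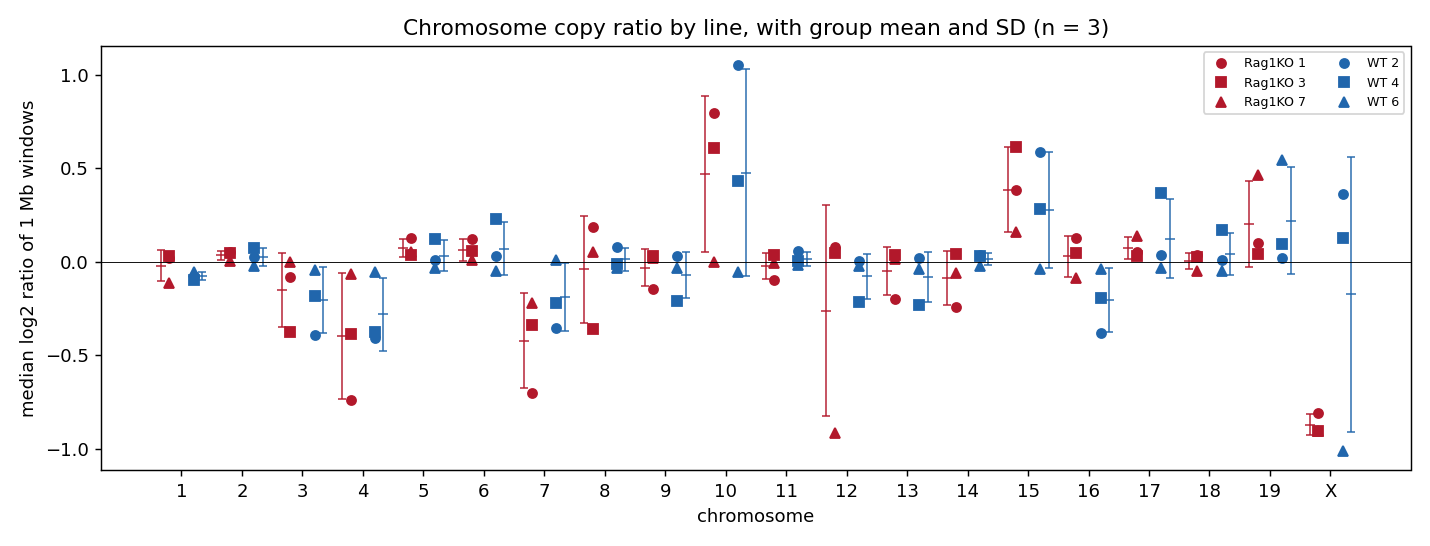
Median log2 copy ratio per chromosome (vertical axis) for chromosomes 1 to 19 and X (horizontal axis). Each symbol is 1 line, red for Rag1KO and blue for WT, and the bars are the group mean ± SD (n = 3). The groups overlap on each of the 20 chromosomes.

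Large parts of the genome were altered in both host groups. The share of autosomal windows in segments at least 0.2 from 0 was 33.3%, 36.2% and 16.3% in Rag1KO 1, 3 and 7 and 36.6%, 47.5% and 8.77% in WT 2, 4 and 6. No normal DNA set the level of 0. Relative to the 6-line median the shares were 22.8%, 18.5% and 19.5% against 21.8%, 16.5% and 24.6%, so WT 6 had the lowest share by the first measure and the highest by the second. That median is itself shifted where most lines were altered. For example, chromosome 4 lay at least 0.2 below 0 in 4 lines and chromosome 7 in 5 lines. WT 6 was at -0.06 and 0.01 on these chromosomes, so the second measure can count levels near 0 as altered. Its highest share there does not show that WT 6 was the most altered line. Gains took 12.1% ± 4.25 of windows in the Rag1KO lines and 14.8% ± 7.66 in the WT lines (SD, n = 3), and losses 16.5% ± 6.60 and 16.2% ± 12.5. Copy ratio profiles were most alike in Rag1KO 3 and WT 2, lines from different hosts (Pearson r = 0.88 across 2167 autosomal windows, which are not independent replicates). Windows that are high in several lines enter r, the altered share and the number of segments. An example is 98000001 to 99000000 on chromosome 2, at 6.52 in Rag1KO 3 and 6.85 in WT 2. These measures therefore do not reflect changes of the tumours alone.

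The altered share averaged 28.6% ± 10.7 in the Rag1KO lines and 31.0% ± 19.99 in the WT lines (SD, n = 3), which differed by less than the spread between lines (exact permutation p = 0.8). Lines held 194 ± 6.81 and 196 ± 16.8 segments (exact permutation p = 0.9). Pairs of lines within a host group had a mean r of 0.56 and pairs between groups 0.64, a difference of -0.08 (exact permutation p = 0.2 over 10 splits). The difference in altered share turned to -4.98 percentage points with a bound of 0.3. It was 13.5 without WT 6, -5.90 without WT 4, -3.76 without Rag1KO 7 and -0.43 without WT 2. The difference in segments (1.33) was -7.83 without WT 4, and 22.3 relative to the 6-line median (exact permutation p = 0.1, an alternative chosen after seeing the data). That in profile similarity was -0.26 with depth-based values (exact permutation p = 0.2).

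High copy gains of chromosome 10 lay in different places in different lines. Rag1KO 1 had a block at 112000001 to 118000000 with a median copy ratio of 2.91, or 7.53-fold, against at most 1.15 in the other lines. The block held Mdm2, the ubiquitin ligase that restrains p53 (gene ID 17246, 117688875 to 117710758, copy ratio 2.79), Lyz2, which encodes a lysozyme (3.19), and Glipr1l3 (3.03). Among 1 Mb windows, WT 4 had narrow peaks in those starting at 68000001, 78000001 and 89000001, with medians of 2.96, 2.89 and 3.02. They covered Arid5b (3.20), Pfkl, the liver-type phosphofructokinase of glycolysis (gene ID 18641, 77986947 to 78009807, copy ratio 2.90), and Gas2l3 (3.15). A scan of single bins, given under the other observations, found further high bins of WT 4 on chromosome 10. They lay in Ptprk (2.59 to 3.35), Tbc1d32 (2.25 to 3.13), Stox1 (2.62 to 3.36) and Mon2 (2.83), so the window peaks are not all of its gains.

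Deep losses included Cdkn2a in WT 4 and WT 6, Pira2, a paired immunoglobulin-like receptor gene, in Rag1KO 3 (-2.29), and Eif3j2 in WT 6 (-4.44). Diaph2 on X was at -2.15 in Rag1KO 1, where X as a whole was at -0.81. The low Pira2 bins lay near low bins of Pirb, Gm15448 and Gm14548 in the same line. Whether reads shared with related genes lowered Pira2 or Eif3j2 was not tested, so their values are uncertain. All 4 Cdkn2a bins were at depth 0 in WT 4, and 3 of 4 in WT 6 together with the bin of Cdkn2b, the neighbouring cell cycle inhibitor. The Cdkn2b bin had 80.7 reads in WT 4. In WT 6 the remaining Cdkn2a bin (89281986 to 89282111, 139.9 reads) lay between bins at depth 0 on both sides, unlike in WT 4. The labels name no tumour model and do not say whether any line carried an engineered Cdkn2a allele, so the values do not show whether the loss arose in the tumours.

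Genes at or under -1.5 numbered 4, 6 and 5 in Rag1KO 1, 3 and 7 and 21, 36 and 10 in WT 2, 4 and 6, or 5 ± 1 against 22.3 ± 13.1 (SD, n = 3, exact permutation p = 0.1, the smallest possible). Y genes such as Ddx3y (-4.96 and -4.99) and Rbm31y (-4.96 and -4.99) entered this count in WT 2 and WT 4. Y bins as a whole had a median depth of 0 in these lines, so their Y genes are not focal losses. On autosomes alone, an alternative chosen after seeing the data, the numbers were 1, 3 and 1 against 0, 15 and 3 (exact permutation p = 0.7). Relative to the 6-line median over all chromosomes, Y included, they were 0, 2 and 0 against 20, 21 and 6 (exact permutation p = 0.1). The difference of 17.3 was 10.5 without WT 4 and -62.3 at a bound of -1.0. That bound lies near the level of X as a whole in the Rag1KO lines (-0.90 to -0.81) and WT 6 (-1.01). Genes at or over 1.0 numbered 271 ± 51.2 and 516 ± 365 (exact permutation p = 0.3), with 927 in WT 2, where chromosome 10 as a whole was at 1.05. Their difference of 245 was 40 without WT 2, 389.5 without WT 6 and 80.3 with depth-based values. Relative to the 6-line median, they numbered 36, 0 and 2 in Rag1KO 1, 3 and 7 and 805, 293 and 9 in WT 2, 4 and 6 (exact permutation p = 0.2). This count included X, which as a whole was at 0.36 and 0.13 in WT 2 and WT 4 and at -1.01 to -0.81 in the other lines. The genes on X were not counted apart, so the count does not measure focal gains alone. Duxf3 (3.67 to 4.78), Smok2b (2.10 to 2.59) and Zfp992 (1.79 to 2.503) were high in all 6 lines, and Srsx was low in all 6 (-3.66 to -1.82). These belong to repeated gene families, as do Speer4c (2.78 in WT 6) and Spin2f (2.65 in WT 2), and their values are uncertain. Rhox8 and Mid1, both on X, and Ugt1a1 completed the genes chosen by the fixed rule outside the lists. Rhox8 was chosen for Rag1KO 7 (-1.56), but was at -1.76 in Rag1KO 1, -1.66 in Rag1KO 3 and -1.67 in WT 6. In WT 2 and WT 4 Rhox8 was at -0.11 and -0.59. Mid1 was at 2.26 in WT 2, 1.14 in Rag1KO 1 and at most 0.85 in the other lines. Ugt1a1 was chosen for WT 6 (2.57), but was over 1.0 in all 6 lines, with 2.15 in Rag1KO 7. In depth-based values relative to the 6-line mean, 21 deep losses or high gains of genes outside the lists no longer reached their bound. They were those of Diaph2 (-1.43), Rhox8 (-0.34), Ugt1a1 (0.77), Zfp992 (0.0087 and 0.26), Smok2b, Duxf3 and Srsx, and of Rag1 in the 3 Rag1KO lines (-1.01 to -0.96), where the group difference of Rag1 stayed at 1.97.

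**Figure D4:**
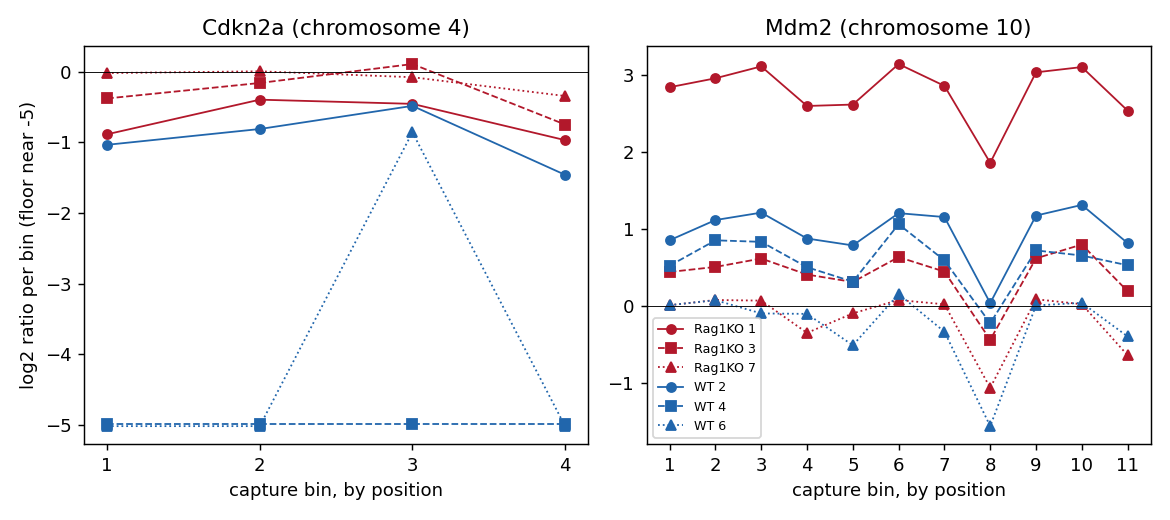
Log2 copy ratio per capture bin (vertical axis, with a lower bound near -5) in order of position (horizontal axis) for Cdkn2a and Mdm2. Each symbol series is 1 line, red for Rag1KO and blue for WT. WT 4 and WT 6 reach the bound in Cdkn2a, and Rag1KO 1 averages 2.79 over Mdm2.

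Gene lists for tumour growth, immune recognition and metabolism, fixed before the data were examined, lay close to the genome's centre in both host groups. The 22 glycolysis genes averaged -0.10 ± 0.03 in the Rag1KO lines and -0.0025 ± 0.057 in the WT lines (SD, n = 3), a difference of 0.10, while the median member differed by 0.027. All 3 WT lines lay above all 3 Rag1KO lines, but narrowly, with WT 6 at -0.067 and Rag1KO 3 at -0.080. Of the 22 members, 0 had groups that did not overlap. The 14 members with a higher WT mean included Pfkl, amplified in WT 4. Of 21 measured tumour suppressors, 13 had a higher and 8 a lower mean in the WT lines, and the list mean differed by -0.13, with Cdkn2a at -2.94, while the median member differed by 0.0064. The 18 genes of MHC class I antigen presentation, which displays peptides to T cells, averaged 0.12 ± 0.05 and 0.16 ± 0.10. The 16 measured genes of interferon gamma signalling averaged 0.04 ± 0.03 and 0.07 ± 0.05.

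The remaining lists differed by -0.0029 (22 oncogenes), 0.05 (13 genes of the MYC network), 0.02 (25 genes of mitochondrial respiration), 0.0041 (15 genes of amino acid uptake and serine synthesis), -0.02 (15 death receptor and NK ligand genes) and 0.04 (18 DNA repair genes). Members at or over 1.0 lay on chromosome 10 with 1 exception. They were Mdm2 and, in WT 2, Cdk4 (1.03), Stk11 (1.18), Lats1 (1.01), Stat2 (1.18), Cs (1.33), Atp5b (1.15), Gls2 (1.13), Shmt2 (1.07), Ulbp1 (1.04), H60b (1.001) and H60c (1.05), with Raet1e at 1.28 in WT 2 and 1.06 in Rag1KO 1, and Pfkl in WT 4. The exception was H2-D1, an MHC class I gene on chromosome 17 (1.08 in WT 4, 0.77 to 0.95 in the other lines), which has close relatives in the genome. In depth-based values relative to the 6-line mean, Mdm2 (2.06) and Pfkl (2.09) stayed over 1.0, while the other 14 values lay at 0.20 to 0.68.

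Of 10 lists, 0 passed. Glycolysis had exact permutation p = 0.1 (adjusted p = 0.8), tumour suppressors exact permutation p = 0.3 (adjusted p = 0.8), and the others exact permutation p of 0.4 to 1. No list member was called by limma over all genes, and 0 were called adjusted over the list alone, where the smallest limma adjusted p was 0.47, among tumour suppressors.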

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

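Mitochondrial bins, which entered no comparison, had a higher mean depth relative to autosomal bins in the Rag1KO lines than in the WT lines. The ratio of median depths was 190, 226 and 92.5 in Rag1KO 1, 3 and 7 (170 ± 69.3, SD, n = 3) and 149, 67.7 and 44.1 in WT 2, 4 and 6 (87.0 ± 55.1). The groups overlapped (exact permutation p = 0.2), and no explanation was tested.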

How the results depend on the processing

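Alternatives with autosomes only (genes, windows, focal counts), with placeholders as deposited, and with segments relative to the 6-line median were chosen after seeing the data. No paired analysis was possible because the host groups share no line numbers. Off-target bins were not run as an alternative, since no bin was marked as off-target. The Rag1 difference stayed positive in all 16 alternatives run for the gene (1.18 to 9.52, the lowest with the median of bins) and that in profile similarity (-0.08) negative in all 13 of its alternatives (-0.26 with depth-based values to -0.057). Unless stated otherwise, the cause was not tested.

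The count of called genes (1) became 0 with trend and robust variances and 0 with the median of bins, and ranged from 1 to 829 when each line was left out. The count of windows (0) ranged from 0 to 151. Both highest values came without WT 6, which leaves WT lines with no Y reads, and the calls lay on X and Y apart from Rag1. Rag1 alone had limma adjusted p values from 1.49e-07 to 0.9999. Chromosomes whose groups did not overlap (0) became 2 without recentring and ranged from 0 to 3 over left-out lines. Lists whose groups did not overlap (1) became 2 without recentring and 2 with the median of members, and ranged from 1 to 2. Smaller groups separate more easily by chance.

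The difference in altered share (2.38 percentage points) became -5.20 with depth-based values, -4.98 with a bound of 0.3, and ranged from -5.90 to 13.5 over left-out lines. That in segments (1.33) was 22.3 relative to the 6-line median and 0.67 there with a penalty of 20, and ranged from -7.83 to 8.67 over left-out lines. That in deep losses (17.3 genes) became -62.3 at a bound of -1.0, was 4.33 on autosomes, and ranged from 10.5 to 23.5. That in high gains (245 genes) was 80.3 with depth-based values and ranged from 40 to 389.5.

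List differences also turned. Oncogenes (-0.0029) were at 0.027 without recentring, 0.014 centred on the mode and 0.0019 with the median of members, and ranged from -0.047 to 0.042 over left-out lines. Death receptor and NK ligand genes (-0.02) were at 0.012 without recentring and ranged from -0.088 to 0.027. With the median of members, tumour suppressors were at 0.011, interferon gamma signalling at -0.0039, mitochondrial respiration at -0.035, DNA repair at -0.082, glycolysis at 0.028 and the MYC network at 0.00016. Over left-out lines, tumour suppressors ranged from -0.22 to -0.072, the MYC network from 0.015 to 0.081, DNA repair from 0.0021 to 0.081, interferon gamma signalling from 0.0023 to 0.048, glycolysis from 0.074 to 0.13, mitochondrial respiration ranged from -0.026 to 0.056, amino acid uptake and serine synthesis from -0.038 to 0.044, and MHC class I antigen presentation from -0.0073 to 0.087.

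Depth-based values relative to the 6-line mean remove what all lines share, and single-line values of Srsx (WT 2, 1.03), Duxf3 (Rag1KO 7, -0.55, and WT 6, -0.63) and Smok2b (Rag1KO 3, -0.038) changed sign there. The same values brought 14 gains of list members from over 1.0 to between 0.20 and 0.68, among them Cdk4 (0.59), Stk11 (0.59), Cs (0.65), H2-D1 (0.20) and Raet1e in Rag1KO 1 (0.34). Without recentring 5 of them lay at 0.96 to 0.998, and centred on the mode 3 at 0.99 to 0.998. The group difference of Smok2b was -0.034 with the median of bins.

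Group differences of uncalled genes changed sign over left-out lines. Ranges were -1.17 to 0.31 (Mdm2), -0.46 to 0.035 (Lats1), -0.49 to 0.083 (H60b), -1.08 to 0.41 (Lyz2), -1.19 to 0.34 (Glipr1l3), -0.072 to 0.28 (Zfp992), -0.075 to 0.085 (H2-D1), -0.033 to 1.32 (Pira2) and -0.13 to 0.11 (Smok2b). They were -0.27 to 0.28 (Cdk4), -0.082 to 0.49 (Stk11), -0.23 to 0.39 (Stat2), -0.19 to 0.38 (Cs), -0.22 to 0.39 (Atp5b), -0.24 to 0.31 (Gls2), -0.26 to 0.33 (Shmt2) and -0.052 to 0.55 (Duxf3). Raet1e ranged from -0.47 to 0.072, Ulbp1 from -0.51 to 0.0023, Eif3j2 from -2.30 to 0.43, Speer4c from -0.035 to 0.77 and Ugt1a1 from -0.22 to 0.34. Depth limits bins at 0, whose level depends on the lower bound.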

Other observations

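All tests in this part were chosen after the results were seen, except the test of sequence differences between mouse strains, whose bounds were set before its value was computed. WT 6 had more bins of low signal than the other lines. In a scan of 231230 autosomal bins outside Rag1, each compared with its 51-bin surroundings and with the other 5 lines, 49 bins of WT 6 lay at or under -1.5, on chromosomes 1, 4, 5, 18 and 19. The counts were 0, 17 and 0 in Rag1KO 1, 3 and 7 and 2 and 6 in WT 2 and WT 4, where 4 of the 6 were the Cdkn2a bins. Of the 17 in Rag1KO 3, 16 lay on chromosome 7, in Pirb, Gm15448, Pira2 and Gm14548. Bins that were high by the same distance numbered 33 in WT 4, 14 in WT 6, 1 in Rag1KO 3 and 0 in the other lines. The genes with low bins in WT 6 included Cdkn2a, Cdkn2b, Zfp951, Gbp6, Eif3j2, Eno1b, Morf4l1b and interferon alpha genes. High bins of WT 6 lay between the low interferon bins on chromosome 4, such as those of Gm13276 (3.27) and Gm13285 (2.21 and 2.58). That stretch was therefore not low throughout. Low bins of WT 6 within 2 Mb of each other formed 9 blocks of at least 2 low bins. Of 20 Braf bins, 5 within 39614112 to 39628655 lay on average -0.49 from the other lines in WT 6, against -0.01 for its other Braf bins, with the bound of 0.3 chosen after the values were seen.

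Low depth in WT 6 was argued against by its library, which ranked 1 of 6 by median bin depth. A swap between the host groups was argued against by Rag1, where 0 lines went against their label. Against the chromosome median in place of the surroundings, at most 19.2% of bins in each of the 4 blocks of over 20 bins and 50% in the block of 10 bins on chromosome 18 were at or under -1.5, but joining low bins across gaps admits bins that are not low, so whether longer stretches were lost stays open. In the other 290 bins of the blocks, downward deviations over 0.5 were 47.3 times as frequent as elsewhere in WT 6, 14.4 times in WT 4 and 0 times in the 4 other lines, but the blocks were drawn around low bins of WT 6, so this rate does not decide whether its sequence differs from the reference strain. That explanation, reads shared within gene families and engineered alleles of Cdkn2a or Braf, on which the labels are silent, stay open, and the last 2 were not tested.

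Chromosomes 4 and 7 were low and chromosomes 10 and 15 high in lines from both hosts. Capture bias would give every line a like level, but the 4 chromosomes had a range over the 6 lines of at least 0.65, against 0.10 on chromosome 2, the smallest of any autosome, and 0.99 on chromosome 12, the largest of the others. A shared culture of Rag1KO 3 and WT 2, the most similar pair, was argued against by Rag1, where WT 2 had at least 177.5 reads in each bin at 0 in Rag1KO 3. These levels did not follow the host, with exact permutation p of 0.4 to 1 for the 4 chromosomes. Of the lines at least 0.2 from 0, Rag1KO lines were 2 of 4 on chromosomes 4, 10 and 15 and 3 of 5 on chromosome 7. With so few lines, a smaller effect of the host stays open.

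A hypothesis concerned the size of the chromosome losses in Rag1KO 3 and WT 2. If 4 copies were the usual state of these cultures, a lost copy would lie near -0.42 (log2 of 3 over 4). Of 8 lost autosomes in both lines, 8 lay within 0.1 of that level, between -0.41 and -0.34. A copy gained over 4 would lie near 0.32, and 0 of the 4 gained autosomes lay within 0.1 of it. Of these, 3 lay within 0.1 of 0.58 (log2 of 3 over 2), the level of 1 copy gained over 2 or of 2 copies gained over 4, and chromosome 10 in WT 2 was at 1.05. Outside these autosomes, the 1 segment of at least 20 windows that was 0.2 or more from 0 lay on chromosome 5 in WT 2 (116000001 to 145000000) at 0.29, within 0.1 of 0.32. Loss of 1 of 2 copies in part of the cells may give the level of the losses, so the explanations cannot be told apart from copy ratios alone.

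For the gene comparison, 2 of the 10 splits of the 6 lines into 3 and 3 gave at least 1 call. They were the host grouping itself, with 1 gene, and 1 other split, which gave 280. For windows the host groups gave 0 calls, a number that 10 of 10 splits reach whatever the data, so that count is not informative. The highest other split gave 51. Both highest counts come from the split of Rag1KO 1, Rag1KO 3 and WT 2 against the rest, and all 280 genes and 51 windows lay on chromosome 10. The structure they point to is that chromosome's higher level in these 3 lines, which does not follow the hosts. With 10 splits, a share under 0.05 cannot be reached.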
